A study of Mus musculus with 9 samples.

How the data were processed

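RNA was taken from leg muscle of 9 mice, and sequencing libraries were made from 1 µg of total RNA with a SMARTER mRNA kit, per the labels' protocols. The authors deposited a table of counts per Ensembl gene with 1 column per sample, which holds whole numbers that sum to a different total in each column and were not normalised. They also deposited a table of FPKM values for the same genes and samples (fragments per kilobase, scaled by library size). The genome build was mm10, per the submitters' processing notes; the aligner, the counting tool, the annotation and whether counting used strand are not given in the sources used here. In 10432 genes with at least 100 counts in every library, 99.2% of the ratios of library-scaled counts to deposited FPKM lay within 1% of 1 constant per gene, so both tables describe the same reads. Gene names came from the deposited table, which gives none for 3225 genes; 55154 of 55335 gene IDs also matched a mouse gene name table, and the unmatched IDs held 0.00626% of the counts. Coordinates are from GENCODE vM21 on the same build, 1-based.

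Groups were taken from the treatment labels: control, aspirin, and aspirin with hydrogel, 3 mice each, described as separate animals. The labels give no sex, dose, time after injury or batch. Each sample also carries a code whose meaning is not given; the controls carry code number 9, the hydrogel libraries 8, Aspirin replicates 1 and 2 7, and Aspirin replicate 3 10. No code number is shared between groups, so a handling batch marked by it could not be told apart from treatment. No pair of libraries agreed within sampling noise (the smallest chi-square per degree of freedom over genes was 77.8), so all 9 were counted as separate samples. At these totals, a gene with no count in a library lies below 0.0554 to 0.100 CPM (3 counts per library, on the TMM-scaled library sizes), and such floors cover counting error only.

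The main test was edgeR's quasi-likelihood test (version 4.0.16 in R 4.3.3, robust fit) on the deposited counts of all 9 libraries in 1 fit with group as the only term, TMM scaling, and genes kept by filterByExpr with its minimum count of 10 and total of 15. All 3 pairwise comparisons and a test of any difference were made, with Benjamini-Hochberg adjustment over the 18259 genes and a threshold of 0.05. Levels are CPM, counts divided by the TMM-scaled library size. Standard errors were derived from the quasi-likelihood F, and intervals are 95%. The common biological coefficient of variation was 0.503. Principal components and Spearman correlations used log2 CPM with a prior count of 1 for the 14572 genes averaging at least 1 CPM.

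47 gene lists covering inflammation, cell types of muscle and of the tissues around it, fibre types, metabolism, stress and signalling were fixed before the data were examined and tested with camera from limma 3.58.1 at the preset inter-gene correlation of 0.01, adjusted over the lists. Camera with a correlation estimated from the data, and fry, in its directional and its mixed test, were run beside it. No list called with the preset correlation was called with an estimated one. For lists given with an adjusted p, the median is printed where leaving out 1 library of the groups compared ended the call. It is also printed where library size alone ended the call, or where either moved the median by over 1.5 times. Any other alternative that ended the call is named. Lists given with a median only have the alternatives that ended their call named. Library size alone moved the median of all genes by 0.23, -0.23 and -0.46 in the 3 comparisons. Genes named in the text follow a rule fixed before the data were examined: the genes of largest change past the threshold or, where fewer than 3 pass, the 5 genes of smallest unadjusted p averaging at least 1 CPM, leaving out predicted and pseudogene names; up to 4 members of each list that passed, by smallest adjusted p; and 17 anchor genes of inflammation, myogenesis and atrophy. Gbp11, Homer2, Ntf5, F830016B08Rik, Cxcl5 in the test of any difference, and the genes given per library in the closing observations were chosen after their values were seen.

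The tests were tested on simulated counts for the 18259 genes drawn from the real means and library sizes with 200 genes changed. For aspirin against control edgeR recovered 1.49%, 34.3% and 63.6% of genes changed 2-, 4- and 8-fold with 6 false calls, and DESeq2 (version 1.42.0) recovered 11.9%, 62.7% and 83.3% with 77 false calls. For aspirin with hydrogel against control edgeR recovered 1.49%, 23.9% and 68.2% with 2 false calls and DESeq2 7.46%, 68.7% and 90.9% with 66. For aspirin with hydrogel against aspirin edgeR recovered 0%, 44.8% and 57.6% with 2 false calls and DESeq2 10.4%, 71.6% and 78.8% with 75. In the first of these, 1 list of cell cycle genes raised 2-fold was called by camera at both settings and by fry's directional test, with 0, 0 and 1 false calls among 46 other lists; the simulated genes vary independently, unlike real ones. Similarity of both treatments was set beside 20 simulations of unchanged groups. In these the controls were simulated too and shared by both comparisons, and genes varied independently.

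Alternatives were DESeq2, limma-voom with sample weights, limma-trend on log2 of the deposited FPKM plus 0.1 or 1, DESeq2 size factors and library size alone as scalings, no filter and a filter of 1 CPM in 3 samples, fits on the 6 samples compared, the replicate number as a block, and each library left out in turn. DESeq2 without Aspirin replicate 1 and the quasi-likelihood fit with adjusted deviances were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.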

Results

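Gene expression was measured by RNA sequencing in leg muscle of 9 WT mice (c57b6l, as the labels write the strain). All mice had a hindlimb model that the labels name with both suspension and ischaemia. 3 mice were left untreated as controls, 3 received aspirin against inflammation, and 3 received aspirin together with a peptide hydrogel. Aspirin inhibits the cyclooxygenases that make prostaglandins. Each mouse gave 1 library. Total counts per library ran from about 32197800 to 48170500, and 18259 of the 55335 genes in the count table passed the filter on low counts. Uninjured muscle and the hydrogel without aspirin were not analysed here. Libraries of the group with aspirin and hydrogel are called hydrogel libraries.

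The libraries of a group did not lie close together. On the first principal component, which held 51.9% of the variance of 14572 genes, Aspirin replicate 1 lay at -152 and Hydrogel replicate 3 at 101, while the other 7 libraries lay from -49.2 to 39.2. The median Spearman correlation of Aspirin replicate 1 with the other libraries was 0.780 across genes, against 0.878 to 0.971 for pairs among the other 8. Its 10 most abundant genes took 9.88% of its counts, against 17.7% to 30.2% in the others. Myh4, the myosin heavy chain of the fastest fibres, stood at 2692 CPM (counts scaled by library size) in that library and at 23375 to 122425 CPM in the other 8.

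**Figure D1:**
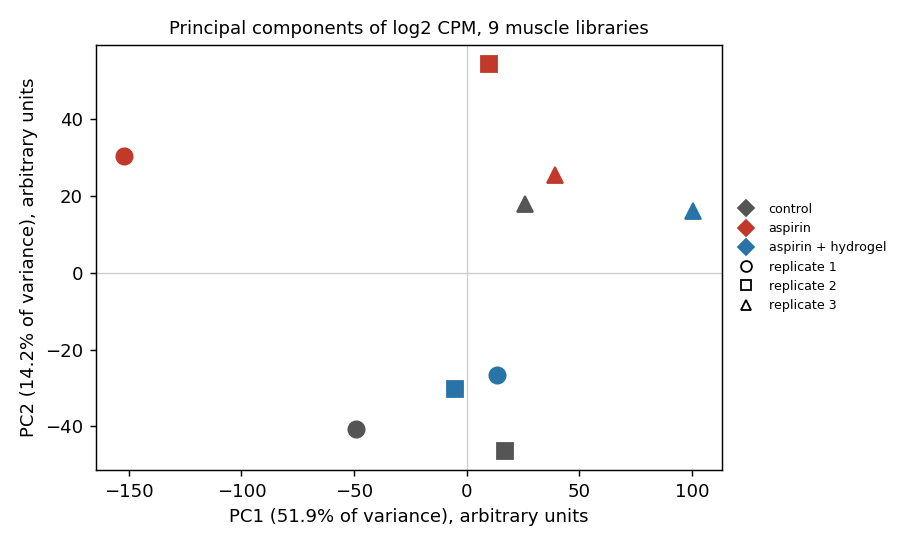
Each point is 1 library, placed by its scores on the first and second principal components of log2 CPM (arbitrary units), with colour for the group and shape for the replicate number. Aspirin replicate 1 lies at -152 on the first component, farther from 0 than the other 8 libraries.

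Aspirin was compared with no treatment to ask what the drug changes in this muscle. Arg1, the arginase of alternatively activated macrophages, stood at 17.7 ± 11.3 CPM (SD, n = 3) in the aspirin libraries and 0.477 ± 0.361 CPM in the controls. Hmox1, the haem-degrading stress enzyme, stood at 88.7 ± 20.6 against 33.2 ± 9.08 CPM, and each aspirin library lay above each control library for both genes. Usp49, a deubiquitinase, went the other way, with 1.39 ± 0.381 CPM after aspirin and 10.6 ± 2.21 CPM in the controls. Aspirin and control libraries were fully separated, in either direction, for 10.98% of all 18259 genes, where chance gives 10%. As lists, macrophage markers and ribosomal protein genes lay higher after aspirin, and endothelial and adipocyte markers lower. No single gene passed an adjusted p of 0.05 in edgeR's quasi-likelihood test.

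Usp49 (ENSMUSG00000090115, chromosome 17, 47630690 to 47686738, plus strand of mm10) had a log2 fold change of -2.93 ± 0.38 (SE, with a 95% interval of -3.78 to -2.07), the smallest unadjusted p of the comparison. It was followed by the homeobox gene Irx5 (ENSMUSG00000031737, chromosome 8, 92357625 to 92376286, plus strand) with -3.07 ± 0.46 and the endothelial gene Apold1 (ENSMUSG00000090698, chromosome 6, 134981718 to 134986836, plus strand) with -2.22 ± 0.35. Next came the cytokine-signalling inhibitor Cish (ENSMUSG00000032578, chromosome 9, 107296026 to 107302784, plus strand) with -2.88 ± 0.46 and Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484, minus strand) with 5.19 ± 0.91. All 5 are annotated as protein-coding, and their adjusted p-values were 0.528 to 0.747 by edgeR. Usp49 shares 4392 exonic bases on the same strand with Gm20517, which averaged 0.488 CPM, and 93 with the antisense gene Tomm6. Exons of Cish overlap those of antisense genes, so the counts of both are uncertain to that extent.

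Monocyte and macrophage markers were higher in 32 of 32 members (median log2 fold change 0.99, adjusted p = 2.3e-12 by camera, adjusted p = 0.678 with an estimated correlation). Among them were Clec4n, a fungal-sugar receptor, at 1.60 ± 0.46, and the integrin gene Itgam at 1.21 ± 0.39. The macrophage median was 0.65 without Aspirin replicate 1. Markers of resident or alternatively activated macrophages were higher in 20 of 22 (median log2 fold change 0.84, adjusted p = 1.6e-07 by camera, adjusted p = 0.482 with an estimated correlation), with F13a1 at 1.22 ± 0.35. Neutrophil markers were higher in 20 of 22 (median log2 fold change 1.52, adjusted p = 7.8e-05 by camera, adjusted p = 0.678 with an estimated correlation). The neutrophil median was 0.999 without Control replicate 2 and 0.26 without Aspirin replicate 1 (not called, adjusted p = 0.375). Inflammatory cytokines and chemokines were higher in 28 of 36 (median log2 fold change 0.88, adjusted p = 9.9e-06 by camera, adjusted p = 0.678 with an estimated correlation). The cytokine median was 1.502 without Control replicate 3, 0.41 without Aspirin replicate 1 (not called, adjusted p = 0.0651) and 1.34 with scaling by library size alone. The neutrophil-attracting chemokine Cxcl5 stood at 17.3 and 25.1 CPM in Aspirin replicates 1 and 3, but at 0.187 CPM in replicate 2, between the lowest and highest control values of 0.112 and 0.443 CPM. Il1b was at 22.2 ± 17.7 CPM after aspirin and 1.66 ± 1.32 CPM in controls. Ptgs2, which encodes inducible cyclooxygenase, was at 2.61 ± 1.55 against 0.427 ± 0.363 CPM, and Ptgs1, the constitutive enzyme, at 4.19 ± 0.410 against 6.43 ± 2.28 CPM. Their adjusted p-values were 0.753, 0.753 and 0.754 by edgeR. The prostaglandin and leukotriene list was called higher by camera (median log2 fold change 0.50). That call was lost with library size alone, with the replicate number as a block, and without Control replicate 2, Aspirin replicate 1 or Aspirin replicate 2.

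Angiogenesis and endothelial markers were lower in 37 of 40 members (median log2 fold change -0.78, adjusted p = 6.0e-18 by camera, adjusted p = 0.515 with an estimated correlation). Cdh5, the cadherin of endothelial junctions, stood at 55.6 ± 22.2 CPM against 157 ± 49.8 CPM, a log2 fold change of -1.49 ± 0.37, and Esam, another junction protein, was at -0.89 ± 0.22. All 25 adipocyte markers were lower (median log2 fold change -1.36, adjusted p = 1.1e-17 by camera, adjusted p = 0.515 with an estimated correlation), including Cfd, which encodes adipsin, at -2.17 ± 0.68. The adipocyte median was -0.82 without Control replicate 2. Genes of fatty acid uptake and oxidation were lower in 33 of 38 (median log2 fold change -0.61, adjusted p = 6.2e-09 by camera, adjusted p = 0.678 with an estimated correlation), among them the acyl-CoA dehydrogenase gene Acadl at -0.80 ± 0.28. The fatty acid median was -0.36 without Aspirin replicate 1. Smooth muscle and pericyte markers were lower in 16 of 19 (median log2 fold change -0.58, adjusted p = 4.7e-06 by camera, adjusted p = 0.515 with an estimated correlation), with the smooth muscle myosin gene Myh11 at -0.92 ± 0.25. The smooth muscle median was -0.28 without Aspirin replicate 1.

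All 77 ribosomal protein genes were higher (median log2 fold change 0.72, adjusted p = 1.1e-17 by camera, adjusted p = 0.678 with an estimated correlation). The ribosomal protein median was 0.21 without Aspirin replicate 1. Heat shock and unfolded protein response genes were higher in 31 of 41 (median log2 fold change 0.50, adjusted p = 3.7e-06 by camera, adjusted p = 0.515 with an estimated correlation), such as Manf at 1.41 ± 0.44 and Creld2 at 1.64 ± 0.51. The heat shock median was 0.29 without Aspirin replicate 2. Cell cycle genes were higher in 45 of 48 (median log2 fold change 0.88, adjusted p = 1.4e-06 by camera, adjusted p = 0.678 with an estimated correlation). The cell cycle median was -0.15 without Aspirin replicate 1 (not called, adjusted p = 0.914). Sarcomere and excitation-contraction genes were lower in 38 of 39 (median log2 fold change -0.31, adjusted p = 1.4e-06 by camera, adjusted p = 0.678 with an estimated correlation). The sarcomere median was -0.54 without Control replicate 1, 0.13 without Aspirin replicate 1 (not called, adjusted p = 0.588) and -1.12 without Aspirin replicate 3. In edgeR, adjusted over the list alone, 1 resident macrophage, 2 neutrophil and 7 endothelial genes passed, against 0 over all genes. In the other lists given above with an adjusted p, 0 genes passed. The myogenic regulators Pax7, Myod1 and Myog had log2 fold changes of -0.38 ± 0.51, 0.50 ± 0.46 and -0.16 ± 0.39, and Vegfa one of -1.01 ± 0.48, none past the threshold in edgeR. The list of satellite cell and myogenic regulators was called lower by camera (median log2 fold change -0.18). That call was lost with library size alone and without Control replicate 3, Aspirin replicate 1 or Aspirin replicate 3.

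Over all genes, 0 of 18259 passed the adjusted threshold in edgeR, and 1183 had an unadjusted p under 0.05 (564 higher, 619 lower). Evenly spread p-values would give 913, and other splits of the libraries compared gave up to 2745. The unadjusted number was 618 without Control replicate 2 and 2733 without Aspirin replicate 3. DESeq2 called 82 (28 higher, 54 lower), and limma-voom called 1, Usp49. In simulated data of this comparison with 200 genes changed, DESeq2 made 77 false calls. In 20 simulations of unchanged groups, where genes varied independently, DESeq2 called 13 to 51. Other splits of the libraries compared gave up to 496 DESeq2 calls. Of the genes named for this comparison, DESeq2 called Usp49, Arg1, Irx5, Cish, Apold1, Cxcl5, Hmox1, Il1b and Cdh5 (adjusted p from 1.0e-08 to 0.0354). 24 of 47 gene lists passed with the preset correlation (10 higher, 14 lower) and 0 with an estimated correlation or with fry's directional or mixed test. 12 of the 24 kept their call without Aspirin replicate 1, where 5 lists were called higher.

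Aspirin with hydrogel was compared with no treatment for the effect of the combination. The hydrogel libraries held less Usp49, at 2.66 ± 0.944 CPM (SD, n = 3) against 10.6 ± 2.21 CPM in the controls, and less of the palmitoyltransferase gene Zdhhc23, at 1.13 ± 0.0915 against 4.54 ± 0.963 CPM. For both genes each hydrogel library lay below each control library. Separation of these groups, in either direction, held for 13.2% of all 18259 genes, where chance gives 10%. As lists, extracellular matrix, neutrophil, adipocyte and cell cycle genes lay lower, and genes encoded by mitochondrial DNA higher. No single gene passed the adjusted threshold in edgeR.

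Zdhhc23 (ENSMUSG00000036304, chromosome 16, 43965033 to 43979791, minus strand) had a log2 fold change of -2.003 ± 0.34 (SE, with a 95% interval of -2.78 to -1.23), and Commd10 (ENSMUSG00000042705, chromosome 18, 46958816 to 47234284, plus strand) one of -1.46 ± 0.26. Usp49 followed with -1.999 ± 0.36, Apold1 with -1.87 ± 0.34 and Zbed6 (ENSMUSG00000102049, chromosome 1, 133655879 to 133660885, minus strand) with 2.23 ± 0.44. Leaving out predicted and pseudogene names, these 5 protein-coding genes had the smallest unadjusted p-values, and their adjusted p was 0.987 by edgeR. Zbed6 is uncertain, since its 5007 exonic bases lie within Gm38394, which stood at 0.436 CPM in Control replicate 3 and 171 CPM in Control replicate 2.

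Extracellular matrix and fibrosis genes were lower in 47 of 49 members (median log2 fold change -0.62, adjusted p = 5.2e-17 by camera, adjusted p = 0.576 with an estimated correlation). Col16a1, a fibril-associated collagen, was at -1.13 ± 0.27, the proteoglycan gene Bgn at -1.31 ± 0.42 and the tenascin gene Tnc at -2.13 ± 0.71. Col1a1, a chain of type I collagen, was at -0.66 ± 0.38. Tendon markers were called lower by camera as well (median log2 fold change -0.69), but not without Control replicate 3. Neutrophil markers were lower in all 22 (median log2 fold change -1.48, adjusted p = 3.0e-06 by camera, adjusted p = 0.676 with an estimated correlation), with the gelatinase gene Mmp9 at -3.87 ± 1.13 and the calgranulin gene S100a8 at -2.05 ± 1.08. The neutrophil median was -0.73 without Control replicate 1 and -2.54 without Hydrogel replicate 1. Red blood cell and platelet markers were also called lower by camera (medians -2.28 and -0.97), but neither without Control replicate 3. Antigen presentation genes were lower in 22 of 23 (median log2 fold change -0.86, adjusted p = 1.0e-05 by camera, adjusted p = 0.676 with an estimated correlation), including the peptide transporter gene Tap1 at -1.13 ± 0.62. The antigen presentation median was -0.51 without Control replicate 1 and -0.45 without Hydrogel replicate 3. T, NK and B lymphocyte markers were called lower by camera too (median log2 fold change -0.90). That call was lost with library size alone, without Control replicate 1 and without Hydrogel replicate 3. Cell cycle genes were lower in 44 of 48 (median log2 fold change -0.91, adjusted p = 1.3e-07 by camera, adjusted p = 0.679 with an estimated correlation), including the mitotic kinase gene Plk1 at -1.09 ± 0.61. The cell cycle median was -0.47 without Control replicate 1. Adipocyte markers were lower in 24 of 25 (median log2 fold change -0.75, adjusted p = 1.2e-06 by camera, adjusted p = 0.676 with an estimated correlation). The adipocyte median was -0.41 without Control replicate 2, -1.26 without Hydrogel replicate 1 and -0.32 without Hydrogel replicate 3. Angiogenesis and endothelial markers were called lower by camera as well (median log2 fold change -0.37), but not without Control replicate 2.

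Immediate early genes were lower in 28 of 33 (median log2 fold change -0.59, adjusted p = 1.2e-05 by camera, adjusted p = 0.676 with an estimated correlation), with Junb at -1.01 ± 0.40 but Fosb at 1.75 ± 0.75. Glucocorticoid response genes were lower in 21 of 24 (median log2 fold change -0.56, adjusted p = 4.9e-05 by camera, adjusted p = 0.676 with an estimated correlation), among them Pdk4, which holds back glucose oxidation, at -2.04 ± 0.77. All 77 ribosomal protein genes were lower (median log2 fold change -0.32, adjusted p = 3.8e-06 by camera, adjusted p = 0.787 with an estimated correlation). The ribosomal protein median was -0.21 without Control replicate 1, -0.51 without Control replicate 2 and -0.55 with scaling by library size alone. All 15 mitochondrially encoded genes were higher (median log2 fold change 0.41, adjusted p = 2.5e-04 by camera, adjusted p = 0.676 with an estimated correlation), with the ribosomal RNA mt-Rnr2 at 1.14 ± 0.65. The mitochondrial median was 0.21 without Control replicate 1, 0.75 without Control replicate 2, 0.18 without Hydrogel replicate 3 and 0.19 with scaling by library size alone. Sarcomere and excitation-contraction genes were higher in 34 of 39 (median log2 fold change 0.29, adjusted p = 0.00708 by camera, adjusted p = 0.787 with an estimated correlation), with the dystrophin gene Dmd at 1.17 ± 0.56. The sarcomere median was 0.055 without Control replicate 1 (not called, adjusted p = 0.433), 0.48 without Control replicate 3, 0.088 without Hydrogel replicate 3 (not called, adjusted p = 0.177) and 0.079 with scaling by library size alone. In edgeR, adjusted over the list alone, 0 genes passed in each of the lists given above with an adjusted p, as over all genes.

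Myod1, the early myogenic regulator, stood at 33.1 ± 6.07 CPM in the hydrogel libraries against 12.8 ± 5.58 CPM, a log2 fold change of 1.37 ± 0.47. Each hydrogel library lay above each control, with an adjusted p of 0.987 by edgeR, and 13.2% of all genes were separated in either direction. Myog, which acts later, was at -0.58 ± 0.39, embryonic myosin Myh3 at -1.20 ± 0.90, and the atrophy ligases Fbxo32 and Trim63 at -0.69 ± 0.87 and -0.41 ± 0.73. Inflammatory cytokines and chemokines were lower in 29 of 36 (median log2 fold change -0.61, adjusted p = 0.00300 by camera, adjusted p = 0.734 with an estimated correlation). The cytokine median was -0.21 without Control replicate 1, -0.98 without Control replicate 2, -0.36 without Control replicate 3 (not called, adjusted p = 0.338), -0.95 without Hydrogel replicate 2 and -0.37 without Hydrogel replicate 3 (not called, adjusted p = 0.354). Monocyte and macrophage markers were lower in 26 of 32 (median log2 fold change -0.38, adjusted p = 0.00906 by camera, adjusted p = 0.787 with an estimated correlation). The macrophage median was -0.25 without Control replicate 1 (not called, adjusted p = 0.182), -0.74 without Control replicate 2, -0.039 without Control replicate 3 (not called, adjusted p = 0.884, camera direction up), -0.68 without Hydrogel replicate 2, -0.016 without Hydrogel replicate 3 (not called, adjusted p = 0.234, camera direction up) and -0.51 with scaling by library size alone (not called). NF-kB response genes were lower in 27 of 35 (median log2 fold change -0.28, adjusted p = 0.0432 by camera, adjusted p = 0.787 with an estimated correlation). The NF-kB median was 0.0022 without Control replicate 1 (not called, adjusted p = 0.285, camera direction down), -0.45 without Control replicate 2, -0.31 without Control replicate 3 (not called, adjusted p = 0.268), -0.31 without Hydrogel replicate 1 (not called, adjusted p = 0.175), -0.44 without Hydrogel replicate 2, -0.15 without Hydrogel replicate 3 (not called, adjusted p = 0.412) and -0.51 with scaling by library size alone (not called). The NF-kB call was also lost with the replicate number as a block and without Aspirin replicate 3. In edgeR, adjusted over the list alone, 0 genes of these 3 lists passed. The inflammatory genes Il1b, Tnf and Ccl2 had log2 fold changes of -1.26 ± 1.12, -0.21 ± 1.14 and -0.21 ± 0.78, and Hmox1 one of -0.32 ± 0.28, none past the threshold in edgeR.

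Over all genes, 0 of 18259 passed in edgeR, and 716 had an unadjusted p under 0.05 (318 higher, 398 lower). Evenly spread p-values would give 913, while other splits of the libraries compared gave at most 595. The unadjusted number was 444 without Control replicate 1, 324 without Hydrogel replicate 3 and 1209 without Aspirin replicate 1. It was 452 with scaling by library size alone and 1168 in a fit on the 6 libraries compared. DESeq2 called 14 (7 higher, 7 lower) and 34 in the real data without Aspirin replicate 1, and limma-voom called 0. In simulated data of this comparison with 200 genes changed, DESeq2 made 66 false calls. In 20 simulations of unchanged groups, where genes varied independently, DESeq2 called 12 to 51. Other splits of the libraries compared gave up to 22 DESeq2 calls. Of the genes named for this comparison, DESeq2 called Zdhhc23, Usp49, Commd10, Apold1, Zbed6 and Mmp9 (adjusted p from 0.00208 to 0.0292). 27 of 47 lists passed with the preset correlation (4 higher, 23 lower) and 0 with an estimated correlation or with fry's directional or mixed test. 17 of the 27 kept their call without Control replicate 3, where the lists called were 9 higher and 13 lower, and 18 without Hydrogel replicate 3. The lists called higher were 2 without Control replicate 1 and 7 without Hydrogel replicate 2.

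The hydrogel group was compared with the aspirin group for what the hydrogel adds to the drug. Arg1 stood at 0.202 ± 0.166 CPM (SD, n = 3) with the hydrogel and 17.7 ± 11.3 CPM with aspirin alone. Hmox1 stood at 26.6 ± 5.96 against 88.7 ± 20.6 CPM, and Lox, the collagen cross-linking enzyme, at 25.0 ± 5.79 against 103 ± 44.5 CPM. For each of these genes the hydrogel libraries lay below the aspirin libraries. Separation of these groups, in either direction, held for 16.2% of all 18259 genes, where chance gives 10%. As lists, inflammatory, macrophage, neutrophil, cell cycle, matrix and ribosomal protein genes lay lower with the hydrogel, and sarcomere and mitochondrial genes higher. No single gene passed the adjusted threshold in edgeR.

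Arg1 had a log2 fold change of -6.39 ± 0.98 (SE, with a 95% interval of -8.61 to -4.17), Lox (ENSMUSG00000024529, chromosome 18, 52516067 to 52529867, minus strand) one of -2.05 ± 0.33, and Hmox1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589, plus strand) one of -1.74 ± 0.29. Fcrls (ENSMUSG00000015852, chromosome 3, 87250758 to 87263738, minus strand) followed with -1.39 ± 0.25, and Brinp3 (ENSMUSG00000035131, chromosome 1, 146494760 to 146902472, plus strand) was the fifth gene by unadjusted p. All 5 are protein-coding, with an adjusted p of 0.453 by edgeR. Brinp3 had no count in the 3 hydrogel libraries and 3.05 ± 2.08 CPM in the aspirin libraries, at least 34.8-fold higher against a floor of 3 counts per library. 30 exonic bases of Lox and 161 of Brinp3 overlap antisense genes, which makes these counts uncertain to that extent.

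Neutrophil markers were lower in all 22 members (median log2 fold change -3.18, adjusted p = 3.5e-11 by camera, adjusted p = 0.499 with an estimated correlation). Hdc, the histamine-producing enzyme, was at -2.13 ± 0.46 and the interleukin decoy receptor Il1r2 at -2.47 ± 0.53. The neutrophil median was -2.01 without Aspirin replicate 1. Red blood cell markers were lower too, in 9 of 10 (median log2 fold change -2.06, adjusted p = 0.00295 by camera, adjusted p = 0.558 with an estimated correlation). The red cell median was -1.60 without Aspirin replicate 2 (not called, adjusted p = 0.0532) and -1.80 without Hydrogel replicate 1 (not called, adjusted p = 0.0523). Monocyte and macrophage markers were lower in all 32 (median log2 fold change -1.37, adjusted p = 2.3e-15 by camera, adjusted p = 0.499 with an estimated correlation), with Clec4n at -2.45 ± 0.48, Msr1, a scavenger receptor, at -2.05 ± 0.53, and the monocyte chemokine receptor Ccr2 at -1.56 ± 0.39. Inflammatory cytokines and chemokines were lower in 31 of 36 (median log2 fold change -1.85, adjusted p = 1.2e-09 by camera, adjusted p = 0.499 with an estimated correlation), including Cxcl5 at -6.60 ± 1.48 and Il1b at -5.003 ± 1.26. The cytokine median was -0.88 without Aspirin replicate 1. Prostaglandin and leukotriene genes were lower in 22 of 27 (median log2 fold change -0.77, adjusted p = 0.00638 by camera, adjusted p = 0.499 with an estimated correlation), with Alox5ap, needed for leukotriene synthesis, at -1.38 ± 0.44 and Ptgs2 at -1.70 ± 0.89. The prostaglandin median was -0.49 without Aspirin replicate 1, -0.44 without Aspirin replicate 2 and -1.29 with scaling by library size alone.

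Extracellular matrix and fibrosis genes were lower in 42 of 49 (median log2 fold change -0.66, adjusted p = 2.6e-12 by camera, adjusted p = 0.499 with an estimated correlation). Col12a1, a collagen of fibril surfaces, stood at 8.04 ± 0.522 against 59.3 ± 34.4 CPM, and Cthrc1 and Thbs2 had log2 fold changes of -2.92 ± 0.66 and -1.11 ± 0.24. The matrix median was -1.13 with scaling by library size alone. Cell cycle genes were lower in 46 of 48 (median log2 fold change -1.91, adjusted p = 2.3e-15 by camera, adjusted p = 0.499 with an estimated correlation), among them the cyclin gene Ccnb1 at -3.04 ± 0.99. The cell cycle median was -0.75 without Aspirin replicate 1. All 77 ribosomal protein genes were lower (median log2 fold change -1.09, adjusted p = 1.1e-27 by camera, adjusted p = 0.499 with an estimated correlation). The ribosomal protein median was -0.59 without Aspirin replicate 1 and -1.71 with scaling by library size alone. Heat shock and unfolded protein response genes were lower in 35 of 41 (median log2 fold change -0.54, adjusted p = 5.4e-06 by camera, adjusted p = 0.499 with an estimated correlation), with Manf at -1.51 ± 0.44. The heat shock median was -0.29 without Aspirin replicate 2 and -0.96 with scaling by library size alone.

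All 39 sarcomere and excitation-contraction genes were higher (median log2 fold change 0.71, adjusted p = 5.0e-10 by camera, adjusted p = 0.558 with an estimated correlation), such as Dmd at 1.48 ± 0.56. The sarcomere median was 0.22 without Aspirin replicate 1 and 1.499 without Aspirin replicate 3. All 15 mitochondrially encoded genes were higher too (median log2 fold change 1.01, adjusted p = 1.6e-09 by camera, adjusted p = 0.499 with an estimated correlation), such as mt-Nd5 at 1.47 ± 0.54. The mitochondrial median was 0.63 with scaling by library size alone. Genes of mitochondrial biogenesis and dynamics were higher in 22 of 25 (median log2 fold change 0.39, adjusted p = 7.5e-05 by camera, adjusted p = 0.499 with an estimated correlation), with the regulator Ppargc1a at 1.07 ± 0.46. The mitochondrial biogenesis median was 0.0087 with scaling by library size alone. Angiogenesis and endothelial markers were higher in 33 of 40 (median log2 fold change 0.38, adjusted p = 5.3e-06 by camera, adjusted p = 0.510 with an estimated correlation), with the phosphatase gene Ptprb at 1.36 ± 0.26 and Cdh5 at 1.18 ± 0.37. The endothelial median was 0.23 without Hydrogel replicate 1 and -0.007 with scaling by library size alone. In edgeR, adjusted over the list alone, 11 neutrophil, 4 macrophage, 13 matrix, 30 cell cycle and 1 endothelial genes passed, and 0 did in the other lists named, against 0 over all genes.

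**Figure D2:**
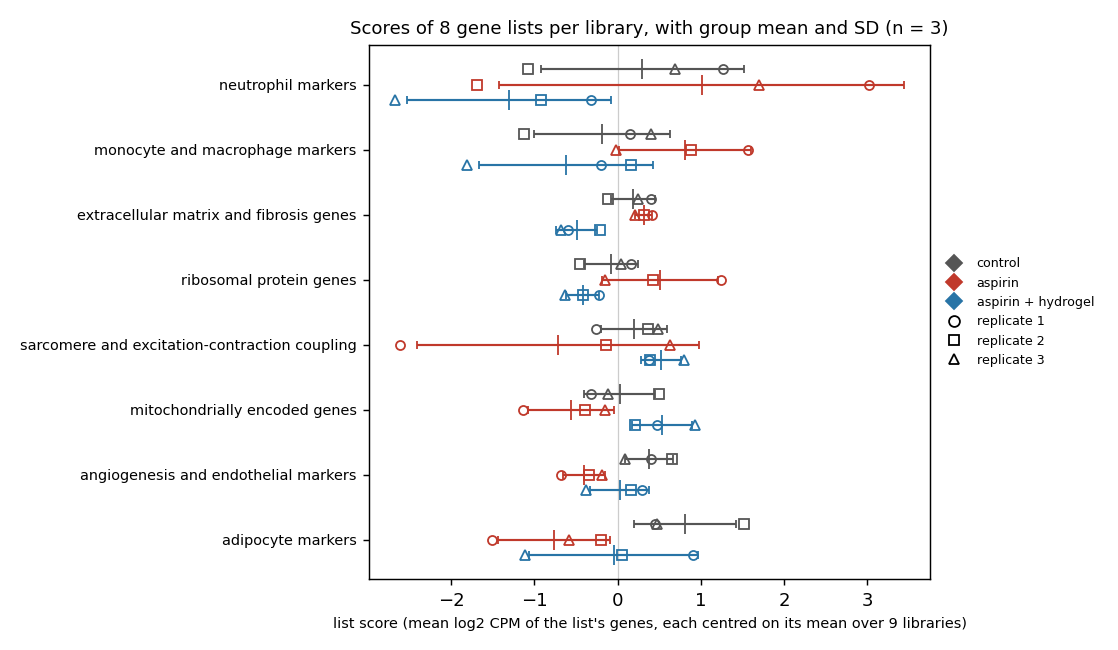
Scores of 8 gene lists per library (mean log2 CPM of a list's genes, each centred on its mean over the 9 libraries), with symbols for libraries and bars for the group mean and SD (n = 3). Aspirin replicate 1 has a neutrophil score of 3.03 and a sarcomere score of -2.62.

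Over all genes, 0 of 18259 passed in edgeR, and 1996 had an unadjusted p under 0.05 (606 higher, 1390 lower). Evenly spread p-values would give 913, and other splits of the libraries compared gave up to 2078. Without Aspirin replicate 3 the unadjusted number was 4239, and 2 genes passed, Homer2 and Ntf5 (both chosen after their values were seen). It was 1005 without Aspirin replicate 1 and 900 without Hydrogel replicate 3. DESeq2 called 148 (36 higher, 112 lower) and 51 in the real data without Aspirin replicate 1, and limma-voom called 0. In simulated data of this comparison with 200 genes changed, DESeq2 made 75 false calls. Its calls in simulated unchanged groups were not counted for this comparison. Other splits of the libraries compared gave up to 257 DESeq2 calls. Of the genes named for this comparison, DESeq2 called Arg1, Brinp3, Cxcl5, Lox, Hmox1, Col12a1, Il1b, Clec4n, Cthrc1, Fcrls, Il1r2, Ptprb, Hdc, Thbs2, Msr1, Ccr2, mt-Nd5 and Ccnb1 (adjusted p from 4.7e-11 to 0.0494). 27 of 47 lists passed with the preset correlation (10 higher, 17 lower) and 0 with an estimated correlation or with fry's directional test. Fry's mixed test, for change in either direction, called 3, the lists of resident macrophages, of matrix genes and of complement and coagulation (each with an adjusted p of 0.0402). 19 of the 27 kept their camera call without Aspirin replicate 1.

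**Figure D3:**
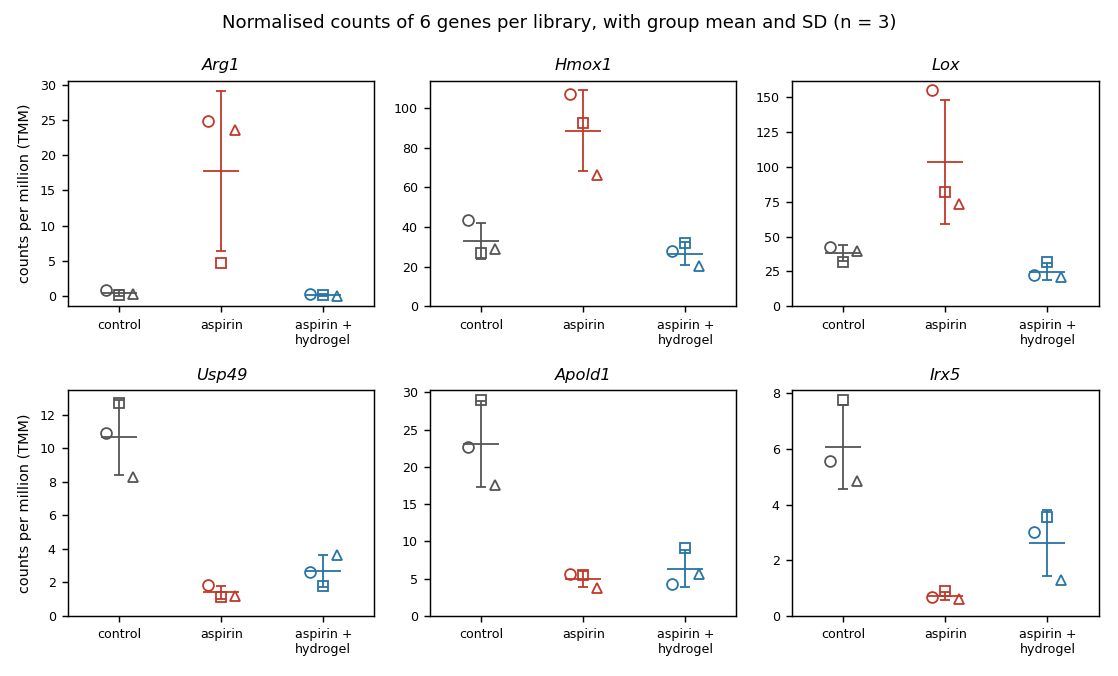
Normalised counts (CPM) of 6 genes on linear axes, with symbols for libraries, shaped by replicate number, and bars for the group mean and SD (n = 3). Arg1 is at 4.71 to 24.9 CPM in the aspirin libraries and at most 0.869 CPM in the others, and Usp49 is at 8.29 to 12.7 CPM in the controls and at most 3.64 CPM in the others.

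Tested for any difference among the 3 groups, 0 genes passed in edgeR (smallest adjusted p = 0.604), 1272 had an unadjusted p under 0.05, and DESeq2's likelihood ratio test called 129. In edgeR 1 gene, Cxcl5, chosen here after its values were seen, passed without Aspirin replicate 2. The log2 fold changes of both treatments against the controls correlated across genes with r = 0.193, although genes are not independent replicates. Simulated unchanged groups, with simulated controls shared by both comparisons, gave r = 0.497 ± 0.015 (SD over 20 simulations). Genes varied independently in these, unlike real ones, so that spread may be too narrow. The real r had an SD of 0.144 over the fits that leave out 1 library. The real covariance was 0.0990 against a simulated 0.241. Without Control replicates 1, 2 or 3 the real r was 0.5002, 0.355 or 0.367, and without Aspirin replicate 1 it was 0.429. Without Aspirin replicate 3 or Hydrogel replicate 2 it was 0.116 or 0.106. The sign was shared by 52.2% of genes, against a simulated 66.7%. At an unadjusted p under 0.05 in both comparisons, 80 genes were lower in both (62.3 in simulations, 13.5 for independent lists), 59 were higher in both (123 in simulations, 9.82 for independent lists) and 4 went opposite ways (2.45 in simulations). Of DESeq2's calls, 3 were shared among the lower genes (Apold1, Gbp11 and Usp49, against 0 to 5 in 20 simulations of unchanged groups, and 0.0205 for independent lists) and 0 among the higher (against 0 to 12 in 20 simulations of unchanged groups, and 0.0106 for independent lists). The real r, covariance, share of equal signs and number higher in both lay below all 20 simulations (r 0.464 to 0.523, higher in both 105 to 142). The number lower in both lay within them (47 to 81). With independent genes in the simulations, these positions do not decide whether the real values depart from unchanged groups. The cause was not tested. The 3 controls cannot be halved with 2 libraries in each part, so the sharing could not be removed. Shared controls without a treatment effect gave 62.3 genes lower and 123 higher in both in the simulations. They may thus account for all of the excess of these genes over independent lists.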

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

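DESeq2 without Aspirin replicate 1 and the quasi-likelihood fit with adjusted deviances were chosen after seeing the data; the other alternatives were set before. For genes past the adjusted threshold, edgeR gave 0 in each comparison and for any difference, also under both other scalings and both other filters. In the 3 comparisons, the 6-sample fits and the adjusted deviances in edgeR and limma-trend on FPKM gave 0 too. DESeq2 gave 82, 14 and 148 genes for aspirin against control, aspirin with hydrogel against control and aspirin with hydrogel against aspirin, and 73, 34 and 51 without Aspirin replicate 1, of which 33, 13 and 30 were shared with its calls on all libraries. For any difference its likelihood ratio test, in place of the Wald test, gave 129. limma-voom gave 1 gene for aspirin against control (Usp49, adjusted p 0.0468) and 0 in the other pairs. Against 1183, 716 and 1996 in edgeR, an unadjusted p under 0.05 was reached by 2520, 1194 and 3656 genes in limma-voom, by 1085 in DESeq2 for aspirin with hydrogel against control, and on filtered FPKM plus 1 or 0.1 by 597 or 565 and 264 or 285 in the first 2 comparisons. Leaving out each library gave 0 to 2 genes for aspirin with hydrogel against aspirin (2 without Aspirin replicate 3, Homer2 and Ntf5, both at adjusted p 0.0464), 0 to 1 for any difference (Cxcl5 without Aspirin replicate 2, adjusted p 0.0341) and 0 in the others. Those 2 genes, Cxcl5 and the block's gene below fall outside the rule for named genes and were chosen after their values were seen. The cause of these differences was not tested.

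The replicate numbers name separate mice and were not used to pair samples. Correlations of same-numbered deviations ran from -0.44 to 0.615, 7 of 9 over 0.1, and 5 of 9 libraries correlated best with their own number. With the replicate number as a block, edgeR called 1 gene for aspirin with hydrogel against aspirin (F830016B08Rik, adjusted p 0.0443) and 0 elsewhere, and 25, 25 and 28 lists; the block changed no other call count by over 1.5 times, and the similarity was 0.253.

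List calls fell from 24, 27 and 27 to 0 in each comparison with an estimated correlation (smallest adjusted p 0.482, 0.576 and 0.499) and to 0 with fry's directional test (0.302, 0.324 and 0.138), which asks a different question. Fry's mixed test called 0, 0 and 3 lists (0.0623, 0.145 and 0.0402); the cause was not tested. Leaving out each library gave 17 to 29, 22 to 30 and 24 to 33 lists. The similarity of both treatments was 0.509 with no filter and 0.106 to 0.5002 with each library left out, against 0.193; the cause was not tested. Of the 24, 27 and 27 lists called, 21, 24 and 24 were called with library size alone and 23, 25 and 27 with the replicate block. DESeq2 size factors moved the median of all genes by less than 0.002. In the camera test no called list turned its direction under a scaling or filter. Left-out libraries turned 6 for aspirin against control (Aspirin replicate 1), 1, 2 and 2 for aspirin with hydrogel against control (Control replicate 1, Control replicate 3 and Hydrogel replicate 3) and 2 for aspirin with hydrogel against aspirin (Aspirin replicate 1), none of them called the other way. With library size alone, the medians of glucocorticoid genes (aspirin against control) and of endothelial, oxidative phosphorylation and clock genes (aspirin with hydrogel against aspirin) changed sign.

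Of 3473 values for 161 named gene and comparison pairs, 3427 kept their direction, 40 turned within 1 SE and 6 reversed. limma-voom gave -0.11 for Il6 and 0.36 for Myog in aspirin against control. With each library left out, Fbxo32 ran from -1.57 (without Aspirin replicate 2) to 0.83 and Trim63 from -0.94 (without Aspirin replicate 2) to 0.68 there, Fbxo32 from -1.52 to 0.88 (without Aspirin replicate 2) in aspirin with hydrogel against aspirin, and Ptgs2 from -0.0065 (without Hydrogel replicate 2) to 1.85 in aspirin with hydrogel against control. None of these passed the threshold, and the cause was not tested. At these depths and group sizes edgeR recovered 0% to 1.49% of 2-fold changes in simulated data.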

Other observations

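The test of sequencing depth was set before its result was seen, and the tests of the splits, of muscle fibre share, of Aspirin replicate 1, of macrophage share, of the description codes, of shared controls, of overlapping reads and of the clock genes after. Lymphocyte genes differed widely between libraries of a group. Igkc, an immunoglobulin light chain, stood at 6006 CPM in Aspirin replicate 1 and at 2.77 to 199 CPM in the other 8 libraries. Jchain, made by plasma cells, stood at 919 against 1.23 to 30.8 CPM. Glycam1, expressed by the high endothelial venules of lymph nodes, was at 31.1 CPM in Aspirin replicate 1 and 29.8 CPM in Control replicate 1, with no count in Aspirin replicate 2 or Control replicate 3. For aspirin against control the lymphocyte list had a median log2 fold change of 0.11 and was not called (adjusted p = 0.209 by camera, whose direction was down). Without Aspirin replicate 1 the median was -2.61 (adjusted p = 5.7e-14 by camera, adjusted p = 0.799 with an estimated correlation).

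Krt10 and Dsp, a keratin and a desmosome gene of skin, stood at 60.0 and 33.4 CPM in Control replicate 1 and at no more than 1.60 and 3.32 CPM in the other 8 libraries. In aspirin with hydrogel against control, red blood cell markers were lower in 9 of 10 (median log2 fold change -2.28, adjusted p = 3.4e-05 by camera, adjusted p = 0.676 with an estimated correlation), with the globin gene Hba-a1 at 95.3 to 1531 CPM in the controls and 90.1 to 185 CPM with the hydrogel. The red cell median was -1.35 without Control replicate 3 (not called, adjusted p = 0.109). Nup62, a nuclear pore gene, stood at 26.0 to 33.6 CPM in the aspirin libraries, at 6.41 to 7.21 CPM in the controls, and at 7.16, 26.7 and 12.1 CPM with the hydrogel. Its exons overlap those of Atf5 and Il4i1, so its counts are uncertain to that extent. Tendon markers were lower in all 11 in aspirin with hydrogel against aspirin (median log2 fold change -1.21, adjusted p = 2.4e-04 by camera, adjusted p = 0.499 with an estimated correlation). Sex-linked genes were higher in all 4 members tested in aspirin with hydrogel against control (median log2 fold change 0.50, adjusted p = 0.00323 by camera, adjusted p = 0.676 with an estimated correlation). The sex-linked median was 0.26 with scaling by library size alone. In edgeR 1 of them, Uty, passed adjusted over the list alone, against 0 over all genes. Y-linked genes had counts in all 9 libraries. Hypoxia targets went both ways, with medians of -0.18, 0.035 and 0.27 in the 3 comparisons, and the list was not called.

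Aspirin replicate 1 stood apart from the other 8 libraries. Sequencing depth is argued against: with libraries thinned to the smallest total, its median correlation with the others was 0.781, below the lowest value of 0.877 among the other 8. Its sarcomere genes differed by -2.95 log2 units from the mean of the other libraries (SD 0.358), so fibre RNA was lower in it. A lower fibre share alone, with other cells in unchanged proportions, would raise the markers of other cell types alike. 4 of 13 such lists lay below the mean of the other libraries by more than their SD. These were endothelial, smooth muscle, adipocyte and nerve markers. TMM scaling, with a factor of 1.63 here against 0.688 to 1.23 in the others, can take off a shared rise. Lying below that mean thus decides nothing by itself, and Des is in both the smooth muscle and the sarcomere list. Another 5 lists, all of white blood cells, lay above that mean by more than their SD. The lists moved apart, from 3.70 log2 units for lymphocytes (SD 1.99) to -1.69 for adipocytes (SD 0.835), which an equal rise alone would not give. This cannot exclude a lower fibre share together with a changed mix of other cells. A difference in that mouse or in the tissue taken stays open, and no biological explanation was tested.

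Arg1, Hmox1 and Lox lay higher in the aspirin libraries than in both other groups, without passing the adjusted threshold in edgeR, while DESeq2 called all 3 in both comparisons. In these libraries Aspirin replicate 1 is not the sole source, since without it the smallest of the 6 changes was 4.30 times its SE. Adjusted p-values without it were 0.846 against the controls and 0.808 against the hydrogel group by edgeR. The pattern was picked from these same libraries, so this is no independent test of it. A larger share of macrophages and a change within cells cannot be told apart. Less their SE, all 3 genes moved more than the marker medians of 0.99 and 1.37 in the 2 comparisons. Arg1 moved by 5.19 ± 0.91 and 6.39 ± 0.98 (SE), beyond the largest marker changes of 2.08 and 2.45 but from near the floor in the other groups. Hmox1 and Lox stayed below those largest changes, and the smallest difference from that marker over the 3 genes was -0.72. A handling batch and the treatment cannot be told apart either, since groups share 0 of the description codes' numbers, and an effect of aspirin stays open as untested.

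Usp49 and Apold1 lay lower in both treated groups than in the controls, without passing the adjusted threshold in edgeR, while DESeq2 called both in both comparisons. Reads counted for the overlapping Gm20517 are argued against for Usp49, since Gm20517 reached at most 0.744 CPM while the group means of Usp49 differed by at least 7.97 CPM. Reads of the shared exons that were counted for neither gene would not show there, and the counting tool is not given. The shared control libraries may account for the pattern, since 2 genes were lower in both comparisons at an unadjusted p under 0.001 and simulated unchanged groups gave 0 to 3. Time of day at sampling and the treatment cannot be told apart. By edgeR, 0 of 19 clock genes had an unadjusted p under 0.05 in both comparisons, and their intervals were too wide to exclude a change. In aspirin against control 1 of the 19 had such a p, against 1183 of all 18259 genes. In aspirin with hydrogel against control 4 did, against 716 of all genes, and 15 of the 19 shared their sign between the comparisons. The endothelial list was called lower by camera in both comparisons too (medians -0.78 and -0.37), and whether Apold1 goes with it was not tested. An effect of aspirin, which both groups received, stays open as untested.

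3 samples against 3 make 10 splits, the real one included, too few for a share under 0.05. Each number of splits given below also counts the real split. A real count of 0 genes past the threshold in edgeR is met by each of the 10 splits whatever they give, so it decides nothing (highest other 0, 0 and 1 in the 3 comparisons). For aspirin against control, 5 gave as many genes with an unadjusted p under 0.05 (real 1183, highest other 2745). DESeq2 gave as many genes in 4 (real 82, highest other 496), and camera as many lists in 7 (real 24, highest other 29). The split that sets Aspirin replicate 1 with Control replicates 1 and 2 gave the 496 genes, which points to a structure of the samples. For aspirin with hydrogel against control, the same counts were 1 (real 716, highest other 595), 3 (real 14, highest other 22) and 4 (real 27, highest other 33). For aspirin with hydrogel against aspirin they were 2 (real 1996, highest other 2078), 2 (real 148, highest other 257) and 3 (real 27, highest other 30). For any difference among the 3 groups, 100 of 280 splits were drawn. The real count of 0 past the threshold in edgeR is again met by all 100 whatever they give (highest other 6). 26 gave as many genes with an unadjusted p under 0.05 (real 1272, highest other 3076), so chance was not excluded.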
